A study of Homo sapiens with 14 samples.

How the data were processed

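RNA was measured in HCT116 cells (a human colorectal carcinoma line) that were uninfected at 0 h or infected with VSV-G pseudotyped HIV at a multiplicity of infection of 1 and harvested 6, 12 and 24 h later. Per the labels' protocols, uninfected cells were harvested 24 h after seeding, and polyadenylated RNA was made into directional libraries. The deposited table holds estimated counts per gene, made with Salmon and merged over libraries per the submitters' processing notes, which give the human build GRCh37. The notes also list Trim Galore, UMI-tools, SAMtools, Picard, StringTie 2.1.4, bedtools 2.29.2, DESeq2 and MultiQC without saying what each did. The strand setting, the annotation release and the Salmon version are not given. The values carry no normalisation: column totals differ, no value is negative, and 8.5% of cells are not whole numbers.

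The labels list 14 samples, with 4 at 12 h and 3 at 24 h, while the table has 3 columns named for 12 h and 4 for 24 h. The 13 columns whose names equal a sample's title were used. The 1 column that matches no sample was used in no step, and 1 sample at 12 h has no column.

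Estimated counts were rounded to whole numbers. Of 57773 genes in the table, 51996 carry a symbol. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13018 genes, 349 of them without a symbol, with 99.86% of all counts. Gene types and transcript lengths came from GENCODE 29, whose build differs, by gene identifier, and no coordinates were used. Libraries were scaled by TMM, and 1 edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was fitted to the 13 libraries with the time points as groups. The common biological coefficient of variation was 7.06%. The tests were 1 over the 4 time points and 5 contrasts: 6, 12 and 24 h against 0 h, 12 h against 6 h and 24 h against 12 h. All were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a contrast. The SE of a log2 fold change was derived from the model's test statistic. Total estimated counts per library ran from 6157022 to 24542832, and a count of 0 was read as at most 3 counts, for counting error only.

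Gene lists were written, and the tests, thresholds, groups and most other settings chosen, before the data were examined. There are 29 lists with 867 entries, of which 858 were matched (808 different genes, 47 of them in more than 1 list). Results for 1 list and 2 genes are not reported here. The other lists cover ATM and ATR checkpoint signalling, homologous recombination, the Fanconi anaemia pathway, end joining, excision and mismatch repair, interferon-stimulated genes, nucleic acid sensing, NF-kB and inflammation, HIV restriction factors and host cofactors, G1/S, G2/M and replication-dependent histone genes, apoptosis, the ATF4 and amino acid response, endoplasmic reticulum chaperones, heat shock, sterol and lipid synthesis, hypoxia and glycolysis, immediate early genes, YAP and TEAD targets, Wnt targets, mitochondrially encoded genes, ribosomal protein genes, and colon, blood cell, fibroblast and embryonic kidney markers. The 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Histone messages of the replication-dependent kind mostly lack a poly(A) tail, so their level after poly(A) selection is a background.

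Named genes followed a rule. For each contrast with 0 h these are the 6 largest rises and falls among called genes with a mean log2 CPM of 2 or more whose groups do not overlap, and the 2 members with the smallest adjusted p of each list that passed and of each DNA damage and innate immune list. CDKN1A, MDM2, GADD45A, ATM, ATR, CHEK1, CHEK2, BRCA1, IFNB1, IFIT1 and CXCL8 were always included. For consecutive time points these are the 4 largest each way. The examples given were taken from this list, and MT-ATP8, COL1A1, PAX2 and PAX8 outside their part of the rule were chosen after their values were seen, as was the order in which genes are described.

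The library sets were found after the contrasts had been fitted. For 17 protein-coding genes with a longest transcript under 600 nt and a mean log2 CPM over 3, the median log2 deviation from the mean of all libraries was taken per library, and libraries were parted at the widest gap (0.15; the second widest was 0.12). The limit of 600 nt was chosen after several length classes and 6 h replicate 4 had been looked at. The 359 genes with transcripts of 600 to 1200 nt do not part the sets.

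The other settings tried were DESeq2-type size factors, library totals alone, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, only the 2 groups compared, replicate number as a block, each library left out in turn, an estimated correlation and a threshold of 0.01 for shared calls. Libraries thinned to equal totals, protein-coding genes alone, the library set as a term and the libraries of 1 set alone were added after the data had been seen. Shared calls were set against 20 simulations in which no group differs. The pipeline was tested on simulated data with changes of 1.5, 2 and 4-fold: 2-fold changes were recovered for 76.1% of genes at 6 h, 83.6% at 12 h and 92.5% at 24 h against 0 h, and false calls were 5.2%, 4.07% and 7.94% of calls. Each gene was simulated with the same spread in all libraries, without library sets and without a deviant library. These shares therefore do not give the false calls in the data.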

Results

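HCT116 cells, a human colorectal carcinoma line, were infected with HIV particles bearing the envelope protein of vesicular stomatitis virus (VSV-G), which lets the virus enter cells that lack the usual HIV receptor. Polyadenylated RNA was sequenced from uninfected cells harvested at 0 h and from cells harvested 6, 12 and 24 h after infection at a multiplicity of infection of 1. The comparison uses 13 libraries: 3 uninfected, 4 at 6 h, 3 at 12 h and 3 at 24 h. Total estimated counts per library ran from 7727481 to 11139245 at 0 h and from 7547895 to 10347754 at 6 h. They ran from 7754269 to 11528174 at 12 h and from 6157022 to 24542832 at 24 h, the last in 24 h replicate 3. All uninfected libraries date from 0 h, so every comparison with them joins infection with the time that passed in culture. The share of cells that took up virus was not examined here, so each value is an average over all cells of a sample. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples. Levels are given below as CPM (counts scaled to a common library total after TMM normalisation), mean ± SD, with n = 3 at 0, 12 and 24 h and n = 4 at 6 h. Changes are log2 fold changes with their standard error (SE).

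**Figure D1:**
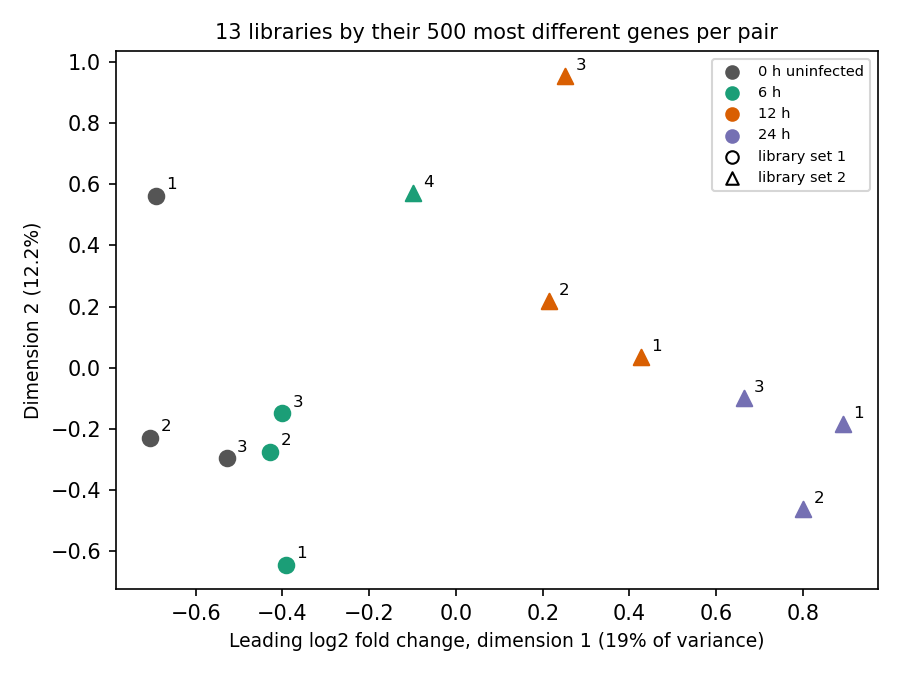
Distances between the 13 libraries by their most different genes, dimension 1 (19% of the variance) against dimension 2 (12.2%), each axis a leading log2 fold change. Each point is 1 library, coloured by time point and shaped by library set, with its replicate number beside it.

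Over the 4 time points, 5306 of 13018 tested genes (40.8%) differed between groups by edgeR's quasi-likelihood test. The libraries also parted in a way that the time points do not explain. MT-ATP8, a mitochondrially encoded subunit of ATP synthase, lay between 241 and 499 CPM in the 3 uninfected libraries and 6 h replicates 1 to 3. It lay between 1020 and 1300 CPM in 6 h replicate 4 and all 12 h and 24 h libraries. These are called library set 1 (6 libraries) and library set 2 (7 libraries). The labels do not name them, and they were found from the level of short transcripts after the comparisons had been fitted. MT-ATP8 was chosen to show them after its values were seen, so it is an example and not separate evidence. Every comparison of 12 h or 24 h with 0 h crosses the sets, 24 h against 12 h lies within set 2, and 6 h against 0 h lies within set 1 once 6 h replicate 4 is left out. The same measure also parted the groups inside set 1. The median log2 deviation of short transcripts lay at -0.16 to -0.04 in the uninfected libraries and at -0.38 to -0.28 in 6 h replicates 1 to 3, a gap of 0.12 against 0.15 between the sets. Values within set 1 are therefore not free of a difference in short transcripts. With the library set as a term in the model, called set-adjusted below, 3332 genes differed over the 4 time points. A single library, 6 h replicate 4, links the sets. Each set-adjusted value for 12 h or 24 h against 0 h, or for 12 h against 6 h, therefore rests on it.

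**Figure D2:**
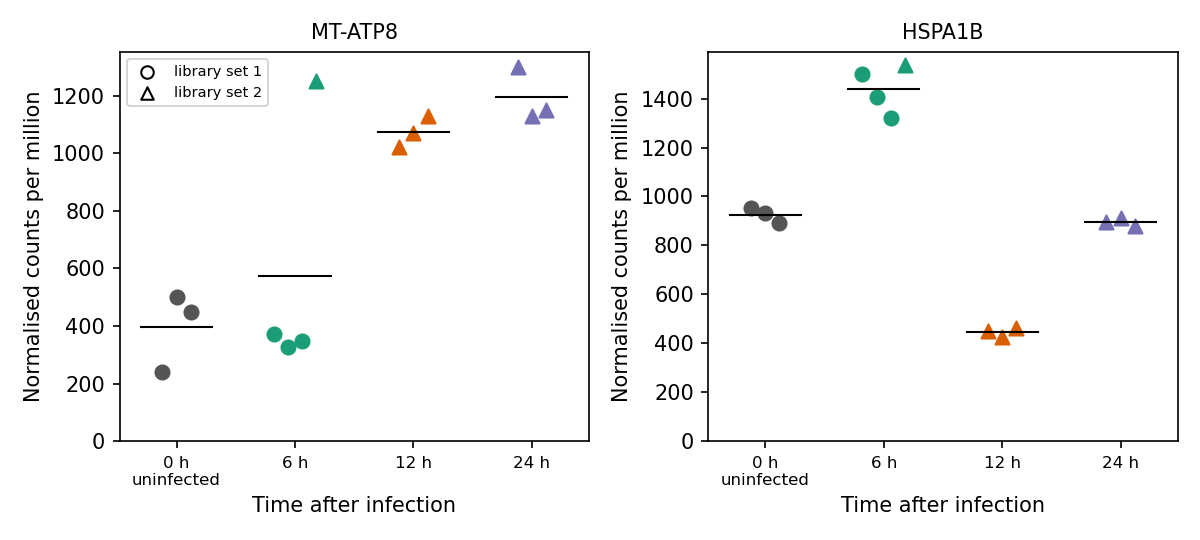
Normalised CPM of MT-ATP8 and HSPA1B in each library by time after infection, 1 point per library, lines at group means and shapes for library sets. MT-ATP8 lies at 241 to 499 CPM in set 1 and at 1020 to 1300 CPM in set 2, while HSPA1B in 6 h replicate 4 lies with the other 6 h libraries.

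The series asks what infection does to the DNA damage response. CDKN1A (ENSG00000124762), the cell cycle inhibitor p21, measured 92.2 ± 3.88 CPM in uninfected cells, 86.7 ± 5.65 at 6 h, 76.9 ± 2.39 at 12 h and 84 ± 4.46 at 24 h. Its log2 change was -0.09 (SE 0.059, edgeR adjusted p = 0.428) at 6 h, -0.26 (SE 0.064, edgeR adjusted p = 0.0138) at 12 h and -0.14 (SE 0.063, edgeR adjusted p = 0.1) at 24 h. The 12 h fall was -0.15 when set-adjusted (edgeR adjusted p = 0.517) and missed the threshold without 12 h replicate 2 (edgeR adjusted p = 0.0649). MDM2, a ubiquitin ligase, stood at 177 ± 5.76 CPM in uninfected cells and at 197 ± 13.6, 199 ± 8.07 and 173 ± 3.36 CPM at 6, 12 and 24 h, with edgeR adjusted p of 0.111, 0.0632 and 0.691. At 6 h MDM2 passed when set-adjusted (log2 change 0.2, edgeR adjusted p = 0.0255) and without 6 h replicate 4 (edgeR adjusted p = 0.0264), but not within set 1 (0.2, edgeR adjusted p = 0.1). These fits are not separate checks. Each takes the change from the same set 1 libraries, and they differ in the libraries used to estimate the spread. GADD45A, a growth arrest gene, was 38.8 ± 4.99 CPM in uninfected cells, 30.7 ± 1.72 at 6 h, 35.5 ± 3.02 at 12 h and 25.9 ± 0.909 at 24 h. It was lower at 24 h (log2 change -0.59, SE 0.093, edgeR adjusted p = 0.000223), and set-adjusted GADD45A gave -0.61 (edgeR adjusted p = 0.0277). At 12 h it did not pass (-0.13, edgeR adjusted p = 0.372). At 6 h it passed (-0.34, edgeR adjusted p = 0.0343), but not within set 1 (-0.35, edgeR adjusted p = 0.111). The 6 h call was also lost without any of 4 libraries, 0 h replicates 1 and 2 and 6 h replicates 1 and 3 (edgeR adjusted p from 0.0819 to 0.166).

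GDF15, a secreted stress cytokine, rose at 24 h from 24.3 ± 2.38 to 45 ± 5.7 CPM (log2 change 0.88, SE 0.096, edgeR adjusted p = 7.31e-06). SFN, the 14-3-3 sigma protein, fell at 24 h from 359 ± 43.8 to 207 ± 11.9 CPM (log2 change -0.8, SE 0.082, edgeR adjusted p = 4.07e-06). Set-adjusted these were 0.95 (edgeR adjusted p = 0.00477) and -0.78 (edgeR adjusted p = 0.00277). SFN had already fallen at 6 h (-0.65, SE 0.076, edgeR adjusted p = 0.000389), also within set 1 (-0.64, edgeR adjusted p = 0.0141). CCNG1, cyclin G1, rose at 12 h (0.34, edgeR adjusted p = 0.00166), and its set-adjusted change of 0.22 did not pass (edgeR adjusted p = 0.248).

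Among the damage sensors and checkpoint kinases, ATM rose from 47.9 ± 1.23 CPM in uninfected cells to 61.4 ± 3.41 at 24 h (log2 change 0.37, SE 0.069, edgeR adjusted p = 0.000811), and set-adjusted by 0.49 (edgeR adjusted p = 0.0178). Its changes of 0.04 at 6 h and 0 at 12 h did not pass (edgeR adjusted p = 0.787 and 0.996). ATR changed by -0.06, 0.09 and 0.11 and CHEK1 by -0.01, 0.14 and -0.05, none past the threshold (edgeR adjusted p = 0.579, 0.384 and 0.165, then 0.942, 0.102 and 0.535). CHEK2 changed by 0.07 and 0.04 at 6 h and 12 h (edgeR adjusted p = 0.71 and 0.822) and by 0.25 at 24 h (SE 0.095, edgeR adjusted p = 0.0476). That call turned to -0.07 when set-adjusted (edgeR adjusted p = 0.781). It was lost without any of 5 libraries, 0 h replicates 2 and 3 and 24 h replicates 1, 2 and 3 (edgeR adjusted p from 0.0858 to 0.141). RAD9A, part of the checkpoint clamp, rose from 16 ± 1.14 CPM to 26.4 ± 0.564 at 12 h (log2 change 0.72, SE 0.091, edgeR adjusted p = 0.000187). It stood at 23.3 ± 1.32 at 24 h (0.52, edgeR adjusted p = 0.000509), and RAD9A passed at both times when set-adjusted (0.82 and 0.63, edgeR adjusted p = 0.0248 and 0.0232). CDC25A, a phosphatase that drives entry into S phase, rose at 12 h (0.32, edgeR adjusted p = 0.00335). The set-adjusted change was no smaller (0.41, SE 0.11), but its call was lost (edgeR adjusted p = 0.068). Of the 33 checkpoint genes, 0 rose and 1 fell at 6 h, 5 rose and 3 fell at 12 h, and 6 rose and 2 fell at 24 h (0 and 1, 8 and 4, and 4 and 2 adjusted over the list alone, and 1 and 2, 1 and 0, and 4 and 0 set-adjusted). The list rose as a set at 12 h (camera adjusted p = 0.0322, and 0.0404 set-adjusted). The call was lost without 0 h replicate 2 or 12 h replicate 2 (camera adjusted p = 0.112 and 0.0562) and with an estimated correlation (camera adjusted p = 0.161). At 6 h and 24 h it did not pass (camera adjusted p = 0.896 and 0.407).

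BRCA1 fell from 83.2 ± 1.29 to 68.9 ± 3.12 CPM at 6 h (log2 change -0.27, SE 0.058, edgeR adjusted p = 0.0168). The call was lost within set 1 (-0.25, edgeR adjusted p = 0.0719) and without 0 h replicate 2 or 6 h replicate 3 (edgeR adjusted p = 0.0558 and 0.0533). At 12 h it was -0.2 (edgeR adjusted p = 0.0466), and -0.11 set-adjusted (edgeR adjusted p = 0.64). It missed the threshold without any of 5 libraries, 0 h replicates 1 to 3 and 12 h replicates 1 and 3 (edgeR adjusted p from 0.0671 to 0.182). At 24 h BRCA1 was -0.08 (edgeR adjusted p = 0.319). Of 33 homologous recombination genes, 0 rose and 3 fell at 6 h, 6 rose and 1 fell at 12 h, and 5 rose and 3 fell at 24 h (0 and 4, 6 and 2, and 5 and 2 over the list alone, and 0 and 4, 1 and 0, and 1 and 0 set-adjusted). The set fell at 6 h (camera adjusted p = 0.0374). It did not pass within set 1 (0.136), when set-adjusted (0.113), without 0 h replicate 2, 0 h replicate 3 or 6 h replicate 4 (0.0697 to 0.11), or with an estimated correlation (camera adjusted p = 0.0984). Neither 12 h nor 24 h passed (camera adjusted p = 0.157 and 0.922). The 21 Fanconi anaemia genes gave 0 rises and 0 falls, 4 and 0, and 3 and 4 at 6, 12 and 24 h (0 and 3, 4 and 0, and 4 and 4 over the list alone, and 0 and 1, 1 and 0, and 1 and 1 set-adjusted). The Fanconi set did not pass (camera adjusted p = 0.169, 0.18 and 0.758). The 18 end joining genes gave 0 and 1, 1 and 0, and 1 and 5, the same over the list alone (camera adjusted p = 0.622, 0.82 and 0.659). Set-adjusted the end joining counts were 1 and 1, 0 and 0, and 3 and 0, so the balance at 24 h turned. TP53BP1, which directs breaks to end joining, rose at 24 h (0.34, SE 0.065, edgeR adjusted p = 0.000961). Set-adjusted, TP53BP1 gave 0.46 (edgeR adjusted p = 0.0159). XRCC5, also on the end joining list, fell at 24 h (-0.21, edgeR adjusted p = 0.00427). Its set-adjusted change of -0.19 did not pass (edgeR adjusted p = 0.136). The 48 excision and mismatch repair genes gave 0 and 4, 8 and 5, and 5 and 9 (2 and 5, 9 and 5, and 4 and 8 over the list alone, and 0 and 4, 0 and 0, and 1 and 3 set-adjusted). The excision set did not pass (camera adjusted p = 0.398, 0.0952 and 0.806), but did at 12 h without 0 h replicate 1 (camera adjusted p = 0.023). HLTF, a replication fork remodeller, rose at 24 h (0.36, SE 0.07, edgeR adjusted p = 0.000934). Set-adjusted, HLTF gave 0.55 (edgeR adjusted p = 0.00702).

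IFNB1, the interferon beta gene, had 0 counts in all 13 libraries, which allows at most 0.11, 0.085, 0.11 and 0.0782 CPM over the libraries of 0, 6, 12 and 24 h by a limit of 3 counts, for counting error alone. IFIT1, an interferon-induced gene, was near the floor at 0.411 ± 0.0639 CPM in uninfected cells and 1.19 ± 0.202 at 24 h. Its log2 change was 0.62 at 6 h (edgeR adjusted p = 0.491), 1.43 at 12 h (SE 0.415, edgeR adjusted p = 0.0321) and 1.5 at 24 h (SE 0.4, edgeR adjusted p = 0.00893). Set-adjusted, the IFIT1 changes were no smaller, at 1.67 (SE 0.79) and 1.74 (SE 0.78), but with the larger errors both calls were lost (edgeR adjusted p = 0.31 and 0.15). The 12 h call was also lost without any of 5 libraries, 0 h replicates 1 to 3 and 12 h replicates 1 and 3 (edgeR adjusted p from 0.0525 to 0.111). CXCL8, the chemokine interleukin 8, summed to 14, 4, 3 and 12 counts over the libraries of 0, 6, 12 and 24 h and was too low to test. Of 34 tested interferon-stimulated genes, 0 rose and 2 fell at 6 h, 4 rose and 4 fell at 12 h, and 5 rose and 5 fell at 24 h (0 and 2, 4 and 5, and 5 and 5 over the list alone, and 0 and 2, 0 and 0, and 2 and 0 set-adjusted). PARP12, a zinc finger antiviral protein, fell from 25.1 ± 0.776 to 13.6 ± 2.37 CPM at 6 h (-0.88, SE 0.119, edgeR adjusted p = 0.000998). Within set 1, PARP12 gave -0.79 (edgeR adjusted p = 0.0141). SAMD9, another antiviral factor, rose from 11.4 ± 0.772 to 20.1 ± 2.14 CPM at 24 h (0.84, SE 0.11, edgeR adjusted p = 4.67e-05). Set-adjusted, SAMD9 gave 0.93 (edgeR adjusted p = 0.0105). As a set these genes fell at 6 h (camera adjusted p = 0.02, and 0.046 within set 1). The call was lost when set-adjusted (camera adjusted p = 0.0569), without 0 h replicate 2 or 6 h replicate 4 (0.097 and 0.0577) or with an estimated correlation (camera adjusted p = 0.212). At 12 h and 24 h the set did not pass (camera adjusted p = 0.722 and 0.806).

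The 17 tested nucleic acid sensing and interferon genes gave 0 rises and 1 fall at 6 h, 2 and 1 at 12 h and 3 and 3 at 24 h (0 and 1, 3 and 1, and 3 and 3 over the list alone, and 0 and 1, 0 and 0, and 1 and 0 set-adjusted). This set did not pass (camera adjusted p = 0.896, 0.815 and 0.806). MAVS, the adaptor of cytosolic RNA sensors, rose from 57 ± 6.77 to 83.4 ± 2.53 CPM at 24 h (0.55, SE 0.076, edgeR adjusted p = 6.88e-05). Set-adjusted, MAVS gave 0.73 (edgeR adjusted p = 0.00241). IRF3, a transcription factor that induces interferon genes, was lower at all 3 times (-0.29, -0.4 and -0.27, edgeR adjusted p = 0.0263, 0.00303 and 0.00974). The IRF3 changes were -0.29 within set 1 at 6 h (edgeR adjusted p = 0.1) and -0.42 and -0.29 when set-adjusted at 12 h and 24 h (SE 0.13 for both, edgeR adjusted p = 0.125 and 0.15). Its call at 6 h was lost without 0 h replicate 1 or 6 h replicates 1 or 2 (edgeR adjusted p from 0.0578 to 0.136). At 24 h it was lost without 0 h replicate 1 or 24 h replicate 3 (0.0566 and 0.0553). The 17 tested NF-kB and inflammatory genes gave 0 and 0, 3 and 0, and 3 and 3 (0 and 0, 3 and 0, and 4 and 3 over the list alone, and 0 and 0, 1 and 0, and 1 and 1 set-adjusted). They did not pass as a set (camera adjusted p = 0.896, 0.603 and 0.806). TNFAIP2, an NF-kB target, rose at 24 h (0.45, SE 0.072, edgeR adjusted p = 0.000245). Set-adjusted, TNFAIP2 gave 0.65 (edgeR adjusted p = 0.00342). SDC4, a cell surface proteoglycan, fell (-0.61, SE 0.07, edgeR adjusted p = 1.14e-05). Set-adjusted, SDC4 gave -0.7 (edgeR adjusted p = 0.0022). The 20 tested HIV restriction factors gave 0 and 0, 0 and 1, and 4 and 0 (0 and 0, 0 and 0, and 2 and 0 over the list alone, and 0 and 0, 0 and 0, and 1 and 0 set-adjusted), and the set did not pass (camera adjusted p = 0.596, 0.681 and 0.426). The 25 HIV host cofactors gave 3 and 0, 2 and 1, and 7 and 3, the same over the list alone, and 2 and 0, 0 and 0, and 4 and 0 set-adjusted (camera adjusted p = 0.559, 0.753 and 0.758).

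At 6 h against uninfected cells, heat shock genes rose, and KRT8, KRT18, KRT6A and KRT7 were among the genes that fell. HSPA1B (ENSG00000204388), an inducible HSP70 chaperone, rose from 926 ± 30.8 to 1440 ± 97.6 CPM (log2 change 0.64, SE 0.057, edgeR adjusted p = 5.47e-05). Within set 1, HSPA1B gave 0.6 (edgeR adjusted p = 0.00816). Its near-identical neighbour HSPA1A can share its reads, and the summed level of the pair rose from 936 ± 27.6 to 1460 ± 97.2 CPM. DNAJB1, an HSP70 cochaperone, rose 1.46-fold (0.55, SE 0.051, edgeR adjusted p = 5.9e-05). Within set 1, DNAJB1 gave 0.53 (edgeR adjusted p = 0.00816). In all, 7 of 16 heat shock genes rose and 0 fell (8 and 0 over the list alone). As a set they passed (camera adjusted p = 3.12e-10), also within set 1, where 4 rose and 0 fell (camera adjusted p = 6.16e-06). The set missed the threshold with an estimated correlation (camera adjusted p = 0.095). KRT8 and KRT18, the paired keratins of simple epithelia, fell from 2580 ± 58.7 to 1980 ± 36.7 CPM and from 1130 ± 98.4 to 877 ± 19.8 CPM (-0.38 and -0.37, edgeR adjusted p = 0.000761 and 0.00197). Both passed within set 1 (edgeR adjusted p = 0.0151 and 0.0359). KRT6A, a keratin of stressed and stratified epithelia, was among the 6 largest falls, from 18.8 ± 2.71 to 9.03 ± 1.01 CPM (-1.06, SE 0.139, edgeR adjusted p = 0.000901). Within set 1, KRT6A gave -1.01 (edgeR adjusted p = 0.0141). KRT7 (-0.85, edgeR adjusted p = 0.00276) and the protease KLK10 (-0.94, edgeR adjusted p = 0.00628) fell too and passed within set 1 (edgeR adjusted p = 0.0242 and 0.0465). DZIP3, a ubiquitin ligase, rose from 14.5 ± 0.339 to 24.8 ± 1.22 CPM (0.77, SE 0.102, edgeR adjusted p = 0.000901). Within set 1, DZIP3 gave 0.75 (edgeR adjusted p = 0.0131).

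Of the 11 tested colon epithelial markers 0 rose and 3 fell at 6 h (0 and 5 over the list alone). They fell as a set (camera adjusted p = 6.63e-06, 0.000113 within set 1, and 0.095 with an estimated correlation). G2/M genes moved up, with 8 of 56 higher and 2 lower (15 and 3 over the list alone). The G2/M set passed (camera adjusted p = 0.00243, 0.00655 within set 1, and 0.095 with an estimated correlation). PLK1, a mitotic kinase, rose 1.2-fold (0.26, edgeR adjusted p = 0.00628, and 0.0465 within set 1). G1/S genes moved down, with 1 of 42 higher and 6 lower (1 and 14 over the list alone). The G1/S set passed (camera adjusted p = 0.000397, 0.000482 within set 1, and 0.095 with an estimated correlation). CENPU, a centromere protein on that list, fell (-0.36, edgeR adjusted p = 0.0195, and 0.034 within set 1). Its call was lost without 0 h replicate 2 or 6 h replicates 1, 2 or 3 (edgeR adjusted p from 0.055 to 0.066). Of 28 sterol and lipid synthesis genes 0 rose and 2 fell (0 and 3 over the list alone). The sterol set passed (camera adjusted p = 0.00582, 0.0391 within set 1, and 0.212 with an estimated correlation). FDFT1, squalene synthase, fell (-0.31, edgeR adjusted p = 0.00602, and 0.0367 within set 1). Of 29 genes of the ATF4 and amino acid response 2 rose and 1 fell (5 and 2 over the list alone). The ATF4 set passed (camera adjusted p = 0.0344, 0.0391 within set 1, and 0.37 with an estimated correlation), but not without 0 h replicate 2 or 3 (camera adjusted p = 0.0591 and 0.247). SLC7A11, the cystine transporter, rose from 29.5 ± 2.37 to 47.4 ± 6.29 CPM (0.7, edgeR adjusted p = 0.00271, and 0.0131 within set 1).

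In total 322 genes were higher and 315 lower at 6 h than in uninfected cells, 5 and 6 of them by 2-fold or more. Set-adjusted the counts were 436 and 422, and within set 1, with 6 h replicate 4 left out and fewer libraries in the fit, 76 and 75. Leaving out 6 h replicate 1, 2 or 3 gave 107, 211 or 135 higher and 116, 199 or 112 lower genes. Leaving out 0 h replicate 1, 2 or 3 gave 111, 144 or 495 higher and 123, 173 or 434 lower. TBC1D32 (0.87), KDM7A (0.9), PDK3 (0.76) and ZNF254 (0.93) were among the 6 largest rises and ATG16L2 (-0.86) and the unnamed ENSG00000273184 (-2.43) among the 6 largest falls. Of these 6, 0 passed within set 1, a fit with fewer libraries (edgeR adjusted p = 0.0525, 0.0702, 0.0838, 0.114, 0.0955 and 0.0597). Their changes there were as large or larger, at 0.88, 0.91, 0.82, 0.94, -0.9 and -3.31. All but TBC1D32 also lost their call without at least 2 single libraries. The edgeR adjusted p reached 0.0565 for KDM7A (0 h replicate 2 or 6 h replicate 1) and 0.115 for PDK3 (any but 6 h replicate 4). It reached 0.146 for ZNF254 (0 h replicates 1 and 2, 6 h replicates 1 and 2) and 0.102 for ATG16L2 (0 h replicates 2 and 3, 6 h replicates 1 to 3). For ENSG00000273184 it reached 0.175 (0 h replicates 1 and 2, 6 h replicates 1 to 3).

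At 12 h against uninfected cells, the heat shock genes that had risen at 6 h lay below their starting level. HSPA1B fell from 926 ± 30.8 to 446 ± 17.6 CPM (log2 change -1.05, SE 0.061, edgeR adjusted p = 8.45e-08; -1.18 and 1.02e-05 set-adjusted), and the pair with HSPA1A from 936 ± 27.6 to 450 ± 19.1 CPM. DNAJB1 fell to 187 ± 8.96 CPM (-0.64, SE 0.055, edgeR adjusted p = 5.71e-06). Set-adjusted, DNAJB1 gave -0.68 (edgeR adjusted p = 0.00468). Of the 16 genes 0 rose and 10 fell, the same over the list alone (camera adjusted p = 3.31e-13, and 0.0412 with an estimated correlation). Set-adjusted, 0 rose and 7 fell (camera adjusted p = 3.89e-19). CCND1, the cyclin of early G1, fell from 1600 ± 52.1 to 999 ± 45.4 CPM (-0.68, SE 0.057, edgeR adjusted p = 3.89e-06). Set-adjusted, CCND1 gave -0.66 (edgeR adjusted p = 0.00468). KRT8 fell to 1740 ± 89.4 CPM (-0.56, edgeR adjusted p = 1.07e-05). Set-adjusted, KRT8 gave -0.59 (edgeR adjusted p = 0.00571). KRT6A fell to 4.2 ± 0.895 CPM (-2.18, SE 0.168, edgeR adjusted p = 2.47e-06). Set-adjusted, KRT6A gave -1.92 (edgeR adjusted p = 0.00669). DDIT4, a stress-induced inhibitor of mTORC1, rose from 16.7 ± 1.27 to 33.9 ± 4.3 CPM (1.02, SE 0.099, edgeR adjusted p = 1.3e-05). Set-adjusted, DDIT4 gave 0.95 (edgeR adjusted p = 0.019). DTL, a replication-coupled ubiquitin ligase subunit, rose 1.53-fold (0.61, SE 0.063, edgeR adjusted p = 2.74e-05). Set-adjusted, DTL gave 0.49 (edgeR adjusted p = 0.0318).

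G2/M genes were lower at 12 h, with 1 of 56 up and 19 down (1 and 28 over the list alone). As a set they fell (camera adjusted p = 8.71e-09, and 0.00911 with an estimated correlation). Set-adjusted 0 rose and 2 fell (camera adjusted p = 1.56e-05). TOP2A, topoisomerase II alpha, fell from 373 ± 11.3 to 287 ± 3.69 CPM (-0.38, edgeR adjusted p = 2e-04), though not past the threshold when set-adjusted (-0.27, edgeR adjusted p = 0.0799). G1/S genes were higher, with 13 of 42 up and 0 down (14 and 2 over the list alone). The set rose (camera adjusted p = 0.000577, and 0.0992 with an estimated correlation). Set-adjusted 2 rose and 0 fell and the set did not pass (camera adjusted p = 0.133). Of the ATF4 list 9 rose and 3 fell (14 and 5 over the list alone). The ATF4 set rose (camera adjusted p = 0.00104, and 0.157 with an estimated correlation). Set-adjusted, 2 of its genes rose and 0 fell (camera adjusted p = 0.00948). Of the colon markers 1 rose and 4 fell, the same over the list alone. They fell as a set (camera adjusted p = 0.0192, 0.024 set-adjusted, and 0.292 with an estimated correlation), but not without 12 h replicate 1 or 2 (camera adjusted p = 0.0984 and 0.065). The 17 tested YAP and TEAD target genes gave 0 rises and 4 falls (0 and 8 over the list alone). They fell as a set (camera adjusted p = 0.00194, 0.292 with an estimated correlation, and 0.231 set-adjusted, where 0 rose and 1 fell). The 8 tested Wnt target genes, which include CCND1, gave 0 and 2, the same over the list alone. The Wnt set fell (camera adjusted p = 0.0144, 0.0992 with an estimated correlation, and 0.133 set-adjusted, where 0 rose and 1 fell). Ribosomal protein genes changed direction with the library set. At 12 h 3 of 78 rose and 0 fell (0 and 0 over the list alone). They were higher as a set (camera adjusted p = 0.000577, 0.654 with an estimated correlation, and 0.0776 without 0 h replicate 3). They were lower when set-adjusted (0 up and 4 down, camera adjusted p = 2.41e-16), which does not by itself show a fall. The term rests on 6 h replicate 4, where ribosomal protein genes held 5.35% of counts. In the other 6 h libraries they held 4.251% to 4.639%, at 0 h 4.653% to 5.548% and at 12 h 5.313% to 5.497%. The 13 mitochondrially encoded genes were higher (2 up and 0 down, the same over the list alone) and passed as a set (camera adjusted p = 0.019, and 0.619 with an estimated correlation). The direction of the mitochondrial set changed when set-adjusted (camera adjusted p = 0.231) and without 0 h replicate 1 (0.864). The mitochondrial share of counts in that library was 2.728% against 6.731% and 6.734% in the other uninfected libraries.

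In total 755 genes were higher and 985 lower at 12 h than in uninfected cells, 80 and 53 by 2-fold or more, but set-adjusted the counts were 52 and 115. Across genes the set-adjusted fold changes correlated with the unadjusted ones at 0.564, though genes are not independent replicates. The median standard error grew from 0.103 to 0.176. Leaving out 12 h replicate 1, 2 or 3 gave 419, 406 or 462 higher and 602, 544 or 637 lower genes. Several of the largest changes did not pass when set-adjusted. The pseudogenes SUMO2P21 (-2.5) and RPL21P16 (-2.38) and the unnamed ENSG00000196656 (-2.94) and ENSG00000264281 (-2.37) fell, and MT-ATP8 (1.44), RPL5P34 (1.45), ANAPC1P4 (1.52), ENSG00000213058 (2.05) and ENSG00000224114 (1.83) rose, all with set-adjusted edgeR adjusted p of 0.13 or more. Their set-adjusted changes were -1.3, 7.64 (SE 2.46), 0.47 and -0.6, then -0.4, -0.1, 0.56, -0.4 and -0.34, in the same order. Single libraries also ended 4 of these calls. ENSG00000213058 reached an edgeR adjusted p of 0.084 without 0 h replicate 1 or 12 h replicates 1 or 3. ENSG00000224114 and MT-ATP8 reached 0.0799 and 0.0775 without 0 h replicate 1 or any 12 h library. RPL21P16 reached 0.131 without 0 h replicates 1 or 2 or any 12 h library. BOLA2 had 0 counts in the 12 h libraries, but with its copy BOLA2B it summed to 31.1 ± 9.06 CPM at 0 h and 24.6 ± 2.15 CPM at 12 h. The testis gene SUN3 rose from 2.37 ± 0.21 to 6.11 ± 1.17 CPM (1.36, SE 0.231, edgeR adjusted p = 0.00161), with a set-adjusted change of 1.09 (edgeR adjusted p = 0.189).

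At 24 h against uninfected cells, genes of the amino acid stress response and of sterol synthesis rose together and targets of YAP fell. DDIT4 (ENSG00000168209) rose from 16.7 ± 1.27 to 80.9 ± 5.96 CPM (log2 change 2.26, SE 0.092, edgeR adjusted p = 3.66e-10). Set-adjusted, DDIT4 gave 2.18 (edgeR adjusted p = 3.59e-06). ASNS, asparagine synthetase, rose from 74.4 ± 2.46 to 164 ± 3.53 CPM (1.14, SE 0.049, edgeR adjusted p = 4.06e-10). Set-adjusted, ASNS gave 1.12 (edgeR adjusted p = 3.59e-06). CHAC1, a glutathione-degrading enzyme, rose 5.24-fold from 2.56 ± 1.19 to 13.7 ± 2 CPM (2.39, SE 0.229, edgeR adjusted p = 2.5e-06). Set-adjusted, CHAC1 gave 2.46 (edgeR adjusted p = 0.00415). In all, 20 of the 29 ATF4 and amino acid response genes rose and 1 fell (20 and 2 over the list alone). As a set they rose (camera adjusted p = 1.32e-21, and 9.28e-05 with an estimated correlation). Set-adjusted 15 rose and 1 fell (camera adjusted p = 3.96e-15). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose from 23.3 ± 1.6 to 68 ± 6.1 CPM (1.54, SE 0.083, edgeR adjusted p = 4.95e-09). Set-adjusted, INSIG1 gave 1.59 (edgeR adjusted p = 3.9e-05). FDFT1 rose from 92.9 ± 1.68 to 169 ± 13.7 CPM (0.86, SE 0.057, edgeR adjusted p = 4.28e-08). Set-adjusted, FDFT1 gave 0.82 (edgeR adjusted p = 0.000272). Of the 28 sterol and lipid genes 22 rose and 0 fell, the same over the list alone (camera adjusted p = 5.91e-28, and 0.000219 with an estimated correlation). Set-adjusted 18 rose and 0 fell (camera adjusted p = 3.66e-21). ULBP1, a stress ligand of the NKG2D receptor of natural killer cells, rose from 2.01 ± 0.67 to 9.14 ± 1.51 CPM (2.2, SE 0.231, edgeR adjusted p = 5.13e-06). Set-adjusted, ULBP1 gave 2.34 (edgeR adjusted p = 0.00336). The long noncoding RNA OLMALINC rose from 2.79 ± 0.571 to 10.7 ± 0.0459 CPM (1.95, SE 0.201, edgeR adjusted p = 4.42e-06). Set-adjusted, OLMALINC gave 2.17 (edgeR adjusted p = 0.00449).

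**Figure D3:**
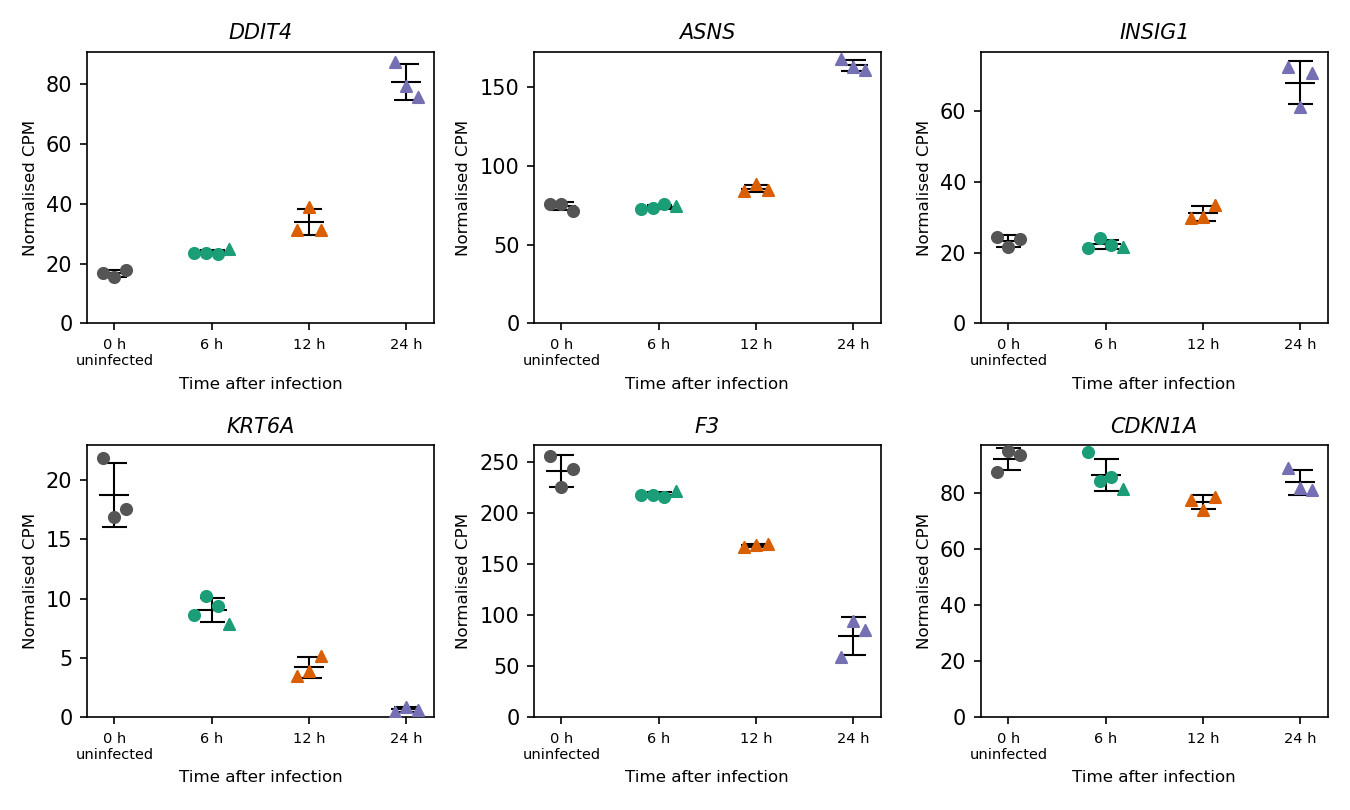
Normalised CPM of DDIT4, ASNS, INSIG1, KRT6A, F3 and CDKN1A in each library by time after infection. Points are libraries, shaped by library set (circles, set 1, and triangles, set 2), and bars are the mean ± SD of 3 libraries (4 at 6 h), where KRT6A fell from 18.8 to 0.666 CPM and DDIT4 rose from 16.7 to 80.9 CPM between 0 h and 24 h.

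KRT6A (ENSG00000205420) fell 28.1-fold at 24 h, from 18.8 ± 2.71 to 0.666 ± 0.214 CPM (-4.81, SE 0.219, edgeR adjusted p = 5.38e-10). Set-adjusted, KRT6A gave -4.56 (edgeR adjusted p = 3.59e-06). TAGLN, the actin-binding protein transgelin, fell 5.05-fold from 28.2 ± 2.46 to 5.68 ± 0.335 CPM (-2.34, SE 0.105, edgeR adjusted p = 5.38e-10). Set-adjusted, TAGLN gave -2.28 (edgeR adjusted p = 3.59e-06). The YAP targets F3, tissue factor, and CCN1, a matricellular protein, fell from 242 ± 15.3 to 79.8 ± 18.4 CPM (-1.58, SE 0.104, edgeR adjusted p = 4.1e-08) and from 42.2 ± 3.29 to 15.9 ± 2.95 CPM (-1.39, SE 0.11, edgeR adjusted p = 3.11e-07). Their set-adjusted changes were -1.61 and -1.66 (edgeR adjusted p = 4.37e-05 and 2.71e-05). Of the 17 YAP and TEAD targets 0 rose and 10 fell (0 and 11 over the list alone). The YAP set fell (camera adjusted p = 3.93e-10, and 0.0258 with an estimated correlation). Set-adjusted 0 rose and 7 fell (camera adjusted p = 1.43e-05). The G2/M and G1/S lists were lower. Of 56 G2/M genes 4 rose and 29 fell, the same over the list alone (camera adjusted p = 6.59e-06, and 0.0258 with an estimated correlation). Set-adjusted, 2 rose and 14 fell (camera adjusted p = 0.000469). CDK1, the mitotic cyclin-dependent kinase, fell from 217 ± 12.1 to 140 ± 5.78 CPM (-0.63, SE 0.056, edgeR adjusted p = 1.24e-06). Set-adjusted, CDK1 gave -0.69 (edgeR adjusted p = 0.000412). Of 42 G1/S genes 3 rose and 13 fell (3 and 14 over the list alone). They fell as a set (camera adjusted p = 0.0338, 0.258 with an estimated correlation, and 0.0668 without 24 h replicate 1). Set-adjusted, 1 rose and 6 fell (camera adjusted p = 0.00638). RRM2, a ribonucleotide reductase subunit, fell from 782 ± 19.6 to 558 ± 4.48 CPM (-0.49, SE 0.046, edgeR adjusted p = 2.13e-06). Set-adjusted, RRM2 gave -0.52 (edgeR adjusted p = 0.000681).

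In total 2167 genes were higher and 2307 lower at 24 h than in uninfected cells, 326 and 59 by 2-fold or more. Set-adjusted the counts were 773 and 960, the correlation of fold changes across genes with and without the term was 0.661, and the median standard error grew from 0.101 to 0.175. Scaled by library totals alone, 2695 were higher and 1646 lower. Heat shock genes no longer differed as a set (2 of 16 up and 4 down, 2 and 5 over the list alone, camera adjusted p = 0.89), with HSPA1B at 895 ± 17.2 CPM. Ribosomal protein genes did not pass as a set (3 up and 3 down, 0 and 0 over the list alone, camera adjusted p = 0.806, and 0.951 with an estimated correlation). They were lower when set-adjusted (0 up and 29 down, camera adjusted p = 2.03e-18 at the preset correlation of 0.01, while the correlation estimated without the term was 0.614). As at 12 h, that value rests on 6 h replicate 4 and does not by itself show a fall. Among the 6 largest changes each way, BOLA2, ENSG00000196656 (-3.78), ENSG00000264281 (-1.93), ANAPC1P4 (1.92) and ZCCHC3 (1.98) did not pass when set-adjusted (edgeR adjusted p = 0.181, 0.731, 0.813, 0.193 and 0.571). Their set-adjusted changes were -2.85 (SE 1.38, against -2.66 unadjusted), -0.37, -0.15, 0.96 and 0.82. Without 0 h replicate 1, 24 h replicate 2 or 24 h replicate 3 BOLA2 lost its call in the unadjusted fit too (edgeR adjusted p from 0.0638 to 0.109), as ZCCHC3 did without 24 h replicate 3 (0.0541). The sum of BOLA2 and BOLA2B was 22.4 ± 2.46 CPM at 24 h.

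**Figure D4:**
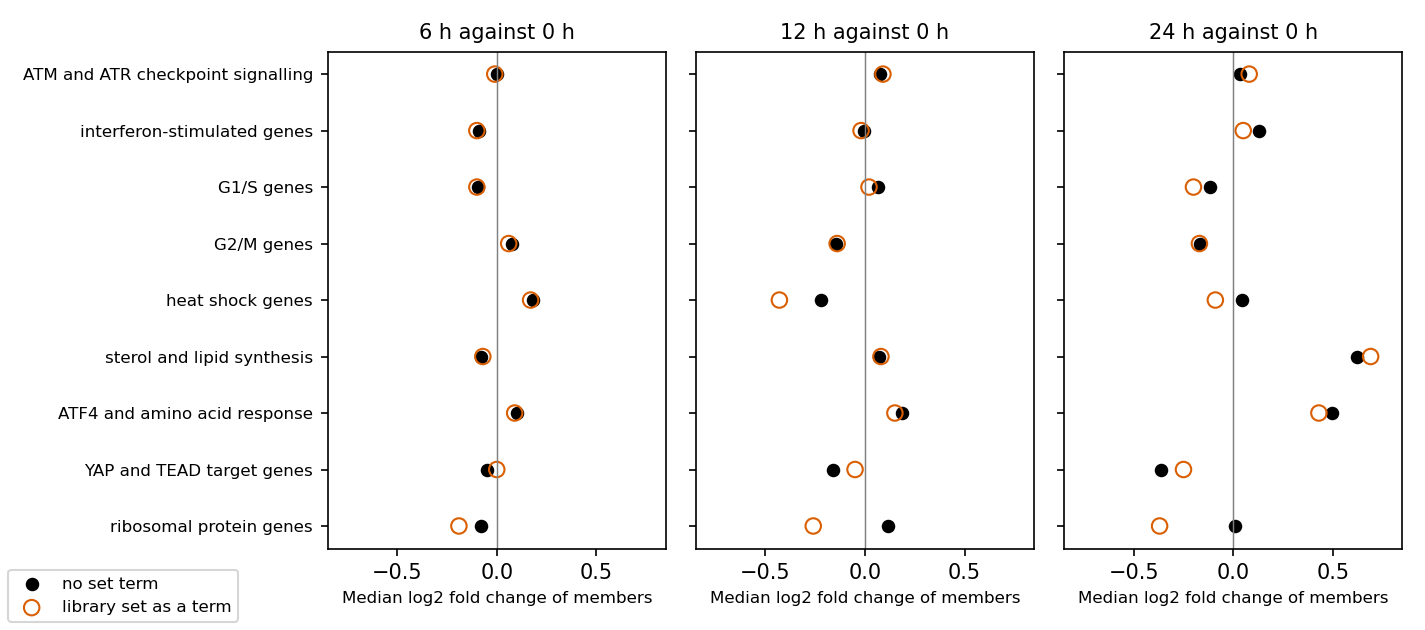
Median log2 fold change of the tested members of 9 gene lists at 6, 12 and 24 h against uninfected cells, without a term for library set (filled points) and with it (open circles). Ribosomal protein genes lie above 0 at 12 h without the term and below 0 with it, while the sterol and ATF4 lists lie above 0 at 24 h in both.

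From 6 h to 12 h, both harvested after infection, the cell cycle lists turned over and the heat shock genes dropped. Of 42 G1/S genes 16 rose and 0 fell (26 and 0 over the list alone, camera adjusted p = 1.11e-15, and 0.00154 with an estimated correlation). Of 56 G2/M genes 0 rose and 25 fell (0 and 32 over the list alone, camera adjusted p = 5.81e-24, and 0.000211 with an estimated correlation). Of 16 heat shock genes 0 rose and 10 fell (0 and 11 over the list alone, camera adjusted p = 5.31e-48, and 0.00039 with an estimated correlation). Set-adjusted the counts were 1 and 0, 0 and 8, and 0 and 9, and the sets passed (camera adjusted p = 1.99e-09, 3.38e-20 and 8.81e-70). Those values hold for the preset correlation of 0.01 only, while the correlation estimated without the term was 0.218 for heat shock genes. Homologous recombination genes moved up (4 of 33 up and 0 down, 11 and 0 over the list alone). Their set test gave a camera adjusted p of 8.23e-05 (0.00541 with an estimated correlation, and 5.39e-05 set-adjusted, where 2 rose and 0 fell). Excision and mismatch repair genes moved up too (6 of 48 up and 0 down, 10 and 0 over the list alone). Their camera adjusted p was 0.00179 (0.0236 with an estimated correlation, and 0.0214 set-adjusted, where 0 rose and 0 fell). Of Fanconi anaemia genes 3 of 21 rose and 0 fell (7 and 0 over the list alone), and of checkpoint genes 5 of 33 rose and 0 fell (8 and 0 over the list alone). Both sets passed (camera adjusted p = 0.00159 and 0.0142), but not with an estimated correlation (camera adjusted p = 0.0768 and 0.0816). Set-adjusted, 2 and 0 of their genes rose and 0 and 0 fell (camera adjusted p = 0.000466 and 0.00739). ELF3, an epithelial transcription factor, rose from 21.8 ± 2.06 to 45 ± 2.86 CPM (log2 change 1.04, SE 0.083, edgeR adjusted p = 1.28e-06). Set-adjusted, ELF3 gave 0.95 (edgeR adjusted p = 0.00264). HSPA1A fell from 20.2 ± 3.07 to 5.32 ± 1.8 CPM (-1.98, SE 0.224, edgeR adjusted p = 0.000102). Set-adjusted, HSPA1A gave -1.73 (edgeR adjusted p = 0.0194). In total 412 genes were higher and 700 lower, and set-adjusted 18 and 78. A fit within set 2 was not made, since its 6 h value would rest on a single library. Leaving out 6 h replicates 1, 2, 3 and 4 gave 130, 208, 185 and 728 higher and 319, 425, 412 and 910 lower genes. Without 12 h replicates 1, 2 and 3 the fit gave 113, 169 and 121 higher and 274, 394 and 285 lower. Sterol genes also moved up (6 of 28 up and 0 down, 7 and 0 over the list alone, camera adjusted p = 9.38e-06, 0.0337 with an estimated correlation, and 2.58e-06 set-adjusted, where 0 rose and 0 fell). YAP targets (0 up and 5 down), Wnt targets (0 and 2), immediate early genes (1 and 7) and endoplasmic reticulum chaperones (0 and 3) moved down (camera adjusted p = 0.000157, 0.00942, 0.000189 and 0.00942). None of these 4 sets passed with an estimated correlation (camera adjusted p = 0.167, 0.0593, 0.0703 and 0.162). Set-adjusted their counts were 0 and 0, 0 and 1, 0 and 3, and 0 and 1 (camera adjusted p = 0.0278, 0.0466, 0.000887 and 0.00244). Ribosomal protein genes moved up (4 of 78 up and 0 down, 25 and 0 over the list alone, camera adjusted p = 5.73e-14, and 0.314 with an estimated correlation) and down when set-adjusted (0 and 0, camera adjusted p = 0.0172).

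From 12 h to 24 h, a comparison within library set 2, the ATF4 and sterol genes rose and the G1/S genes fell. In the fit of set 2 alone, 19 ATF4 genes rose and 1 fell (camera adjusted p = 8.5e-21), and 22 sterol genes rose and 0 fell (8.39e-42). In the same fit 0 YAP targets rose and 9 fell (1.6e-05) and 0 of 42 G1/S genes rose and 27 fell (1.22e-12). With all libraries these counts were 16 and 1, 20 and 0, 0 and 9, and 0 and 24, with camera adjusted p of 1.42e-20, 5.81e-39, 2.47e-07 and 6.03e-12, and with an estimated correlation the YAP set was lost (camera adjusted p = 0.0737). Heat shock genes rose again (10 of 16 up and 0 down, the same over the list alone, and 10 up and 1 down within set 2). Their set passed (camera adjusted p = 7.38e-11, and 0.0369 with an estimated correlation). Of the 5 tested replication-dependent histone genes 4 rose and 0 fell (5 and 0 over the list alone). The histone set passed (camera adjusted p = 0.00294, 0.0369 with an estimated correlation, and 0.00605 within set 2). Ribosomal protein genes fell as a set (0 of 78 up and 1 down, 0 and 0 over the list alone, camera adjusted p = 0.00624, and 0.722 with an estimated correlation). Within set 2, 0 rose and 26 fell (camera adjusted p = 4.43e-08). ONECUT3, a homeodomain transcription factor, rose from 17.6 ± 1.55 to 50.1 ± 1.87 CPM (log2 change 1.52, SE 0.092, edgeR adjusted p = 4.76e-08). Within set 2, ONECUT3 gave 1.53 (edgeR adjusted p = 9.32e-08). CHAC1 and OLMALINC rose by 1.64 and 1.53 (edgeR adjusted p = 0.000121 and 9.28e-05). KRT6A, TAGLN and ARRDC4, an arrestin-domain protein, fell by 2.64, 1.11 and 1.08 on the log2 scale (edgeR adjusted p = 1.24e-05, 1.4e-05 and 5.46e-05). The noncoding BCYRN1, which has many related copies in the genome, fell from 100 ± 23.8 to 38 ± 8.76 CPM (-1.46, edgeR adjusted p = 0.00837, 0.0632 without 24 h replicate 3, and 4.98e-05 within set 2). In total 1122 genes were higher and 1191 lower, and within set 2 1576 and 1730. Scaled by library totals alone the split was 1511 and 642. Without 24 h replicate 3, the deepest library, 614 were higher and 622 lower. Without 12 h replicate 3 the counts were 670 and 686, and the lower count was 765 and 754 without 12 h replicate 1 or 24 h replicate 1.

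The remaining lists passed at no time against uninfected cells, with higher and lower counts at 6, 12 and 24 h as follows. Apoptosis regulators gave 0 and 0, 0 and 3, and 2 and 8 of 27 (4 and 5, 0 and 3, and 2 and 8 over the list alone, and 1 and 0, 0 and 0, and 2 and 4 set-adjusted, camera adjusted p = 0.559, 0.0674 and 0.0633). Without 0 h replicate 3 the apoptosis set passed as lower at 12 h and 24 h (camera adjusted p = 0.0213 and 0.0253). Endoplasmic reticulum chaperones and unfolded protein response genes gave 1 and 0, 0 and 2, and 2 and 5 of 22, the same over the list alone, and 1 and 1, 0 and 1, and 0 and 2 set-adjusted (camera adjusted p = 0.366, 0.209 and 0.659). Hypoxia and glycolysis genes gave 1 and 4, 2 and 5, and 4 and 8 of 32 (2 and 6, 2 and 6, and 4 and 8 over the list alone, and 1 and 4, 1 and 0, and 3 and 4 set-adjusted, camera adjusted p = 0.358, 0.89 and 0.806). Immediate early and MAPK feedback genes gave 2 and 0, 4 and 7, and 4 and 12 of 28 (4 and 1, 6 and 7, and 4 and 12 over the list alone, and 3 and 0, 1 and 2, and 2 and 4 set-adjusted, camera adjusted p = 0.0607, 0.157 and 0.164). They passed without 0 h replicate 2 or 6 h replicate 2 at 6 h (0.0427 and 0.0415), and without 0 h replicate 1 at 12 h and 24 h (0.0202 and 0.0494). Replication-dependent histone genes gave 0 and 0, 0 and 1, and 3 and 0 of 5 against uninfected cells, the same over the list alone, and 0 and 0, 0 and 0, and 1 and 0 set-adjusted (camera adjusted p = 0.973, 0.874 and 0.0633). That set passed at 24 h without 24 h replicate 2 or 3 (camera adjusted p = 0.0457 and 0.0396). Of 14 blood cell markers 0 reached the tested level. Of the others, 1 of 10 fibroblast markers did (COL1A1, 12.5 CPM at 0 h and 20 CPM at 24 h), and 2 of 8 embryonic kidney markers did (PAX2, 4.8 and 9.03 CPM, and PAX8, 4.28 and 2.73 CPM). At 24 h COL1A1 and PAX2 were higher than at 0 h (0.65 and 0.87, edgeR adjusted p = 0.00106 and 0.00287). Set-adjusted, COL1A1 gave 0.65 (SE 0.24, edgeR adjusted p = 0.0785) and PAX2 gave 0.94 (SE 0.37, edgeR adjusted p = 0.101). PAX8 did not pass (edgeR adjusted p = 0.121). At the times not yet given, sterol genes at 12 h gave 3 and 0, and set-adjusted 1 and 0 (camera adjusted p = 0.18 and 0.124), YAP targets at 6 h 1 and 1 (0.973), and Wnt targets at 6 h and 24 h 0 and 1, and 1 and 2 (0.737 and 0.486). Counts were for colon markers at 24 h 2 and 4 (0.321), and for mitochondrially encoded genes at 6 h and 24 h 0 and 0, and 3 and 0 (0.124 and 0.0633). For ribosomal protein genes at 6 h they were 0 and 0, but 0 and 13 set-adjusted and 0 and 4 within set 1. The mitochondrial set passed at 6 h without 0 h replicate 2, 0 h replicate 3 or 6 h replicate 2 (camera adjusted p from 0.00337 to 0.0134). It did not pass with an estimated correlation (0.708) or within set 1 (0.868), where its median log2 change was 0.02 against 0.193. At 24 h it passed without 0 h replicate 2, 0 h replicate 3 or 24 h replicate 3 (0.00984 to 0.0396). It did not pass with an estimated correlation (0.808), and set-adjusted its direction turned (median -0.21 against 0.364, 0 up and 0 down, camera adjusted p = 0.65). At 6 h the ribosomal set was lower (camera adjusted p = 0.00243, 3.47e-16 within set 1, and 0.708 with an estimated correlation). It did not pass without 0 h replicate 1 or 6 h replicate 1 (camera adjusted p = 0.103 and 0.207).

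The 3 comparisons with uninfected cells share their control libraries. Of the genes called at 6 h and at 12 h, 321 were called in the same direction in both (123 higher, 198 lower). That stands against 18.7 and 23.8 for independent lists of those sizes and 0 in 20 simulations of unchanged groups set against the same controls. Unchanged groups give few calls at all, so a simulated count near 0 says little about the shared calls. At 6 h and 24 h 401 were shared (197 and 204, against 53.6 and 55.8, simulated mean 0.05). At 12 h and 24 h it was 1155 (493 and 662, against 126 and 175, simulated 0). Set-adjusted, the shared counts were 91, 379 and 139. The fold changes correlated across genes at 0.512, 0.557 and 0.583, against simulated values of 0.537, 0.536 and 0.498. Their covariances were 0.0766, 0.0997 and 0.122, against simulated 0.0307, 0.0301 and 0.0304. The differences were 0.0459, 0.0696 and 0.092, and for 12 h and 24 h they include a library set. They need not lie beyond the shared controls, since each gene was simulated with the same spread in all libraries. In the data, 0 h replicate 1 differed from the other 0 h libraries by a chi-square per degree of freedom of 24.31 and 26.88. Between those others it was 2.23. With 3 uninfected libraries the controls could not be split, so part of the excess of shared calls may come from them. The count shared by 6 h and 12 h was 133 without 0 h replicate 1, and lay between that and 189 without 0 h replicate 2, 6 h replicates 1 or 3, or 12 h replicate 2. That shared by 6 h and 24 h was 147, 218 and 602 without 0 h replicates 1, 2 and 3, 155, 261 and 163 without 6 h replicates 1, 2 and 3, and 266 without 24 h replicate 3. That shared by 12 h and 24 h was 713 and 651 without 12 h replicates 1 and 2.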

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

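The tests of 6 h replicate 4, of the HSPA1A and HSPA1B copies and of the library sets were chosen only after the results were seen; those of other splits, the abundance trend and time in culture were chosen before.

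In 6 h replicate 4, the unnamed gene ENSG00000264281 stood at 5.94 CPM while the other 6 h libraries lay at 19.5 to 20.8 CPM, and the pseudogene RPL22P1 stood at 25.6 CPM against 8.15 to 9.62. Each gap exceeded Dixon's limit at 95% for a group of 4; 50 results were examined and 2 exceeded it, where chance alone gives about 1 in 20. The level of short transcripts parted this library from the other 6 h libraries and placed it beside the 12 h and 24 h libraries. That it holds a 12 h sample is argued against by its heat shock genes, which lay a median of 0.52 above the 12 h mean on the log2 scale. A candidate explanation is a difference in library preparation or processing between the sets. Transcripts of 600 to 1200 nt, not used to find the sets, were higher in 6 h replicate 4 than in each other 6 h library. The median difference was at least 0.25 (up to 0.33), against at most 0.08 among those libraries. That concerns 1 library only. The limit of 600 nt was chosen after it and several length classes had been looked at, so it is not separate evidence. Relative to the mean of all libraries, these transcripts lay at 0.17, 0.03 and -0.07 in 0 h replicates 1 to 3 (set 1). They lay at -0.05 to 0.03 in the 24 h libraries (set 2). They therefore do not part the sets and cannot decide on a difference between them. No biological explanation of this library was tested.

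By the set test of 12 h against 6 h, 13 lists differed, and 6 of them with an estimated correlation. Those that had also passed against uninfected cells at both times, in opposite directions, were 4: G1/S genes (camera adjusted p = 1.11e-15), G2/M genes (5.81e-24), heat shock genes (5.31e-48) and ribosomal protein genes (5.73e-14). Another split of the 6 h and 12 h libraries also gave 13 lists. For the ribosomal genes the difference changed direction with the library set as a term, and with an estimated correlation it did not pass (camera adjusted p = 0.314). Against uninfected cells, 0 lists passed at 6 h with an estimated correlation. At 12 h G1/S and ribosomal genes did not pass with it (camera adjusted p = 0.0992 and 0.654), nor did G1/S genes with the set as a term (camera adjusted p = 0.133). Heat shock genes were higher at 6 h and lower at 12 h. Reads shared between HSPA1A and HSPA1B are argued against as the whole cause by the other members, whose median log2 change from 6 h to 12 h was -0.29. A difference between the library sets is argued against by the median of -0.52 with the set as a term, which rests on 6 h replicate 4. That library had the highest heat shock level, a median of 0.31 above the mean of all libraries. The other 6 h libraries lay at 0.1 to 0.14, so the size of -0.52, against -0.343 without the term, depends on it. Time in culture or handling cannot be told apart from infection, since 0 uninfected libraries were harvested at 6 h or 12 h, and both stay open.

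At 24 h sterol and ATF4 genes were higher and YAP targets lower. A difference between library sets is argued against as the whole cause by the median log2 changes from 12 h to 24 h within set 2, 0.6 for sterol, 0.35 for ATF4 and -0.24 for YAP genes. A trend of fold change with abundance is argued against by the medians at 24 h against 0 h after that trend was removed, 0.66, 0.55 and -0.32. Time in culture, which brings denser cells and spent medium, cannot be told apart from infection, since 0 uninfected libraries were harvested at 24 h. Infection and time in culture both stay open.

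Other splits of the libraries were counted for each count of genes and, in the contrasts with 0 h, for each count of lists. Each number of splits below includes the real one. A share under 0.05 argued against chance for the 5306 genes over the 4 time points. There, of 60 splits, the real one and drawn others, 1 gave as many, the real one (highest other 5). Such a share argued against chance too for the 637 genes at 6 h (1 of 35, highest other 355). The 9 lists at 6 h (highest other 8) and the 1112 genes from 6 h to 12 h (highest other 1024) also had 1 of 35. That is the lowest share that 35 splits can give. Another split came close to each of the last counts, so chance is not excluded for them. The split with 1024 genes set 6 h replicates 1 to 3 against 6 h replicate 4 and the 12 h libraries, so it follows the library sets. A fit within set 2, whose 6 h value would rest on 1 library, was not made, and with the set as a term 96 genes differed. The 10 splits of the other contrasts are too few for a share under 0.05. Their real counts and highest others were 1740 and 3 genes at 12 h, 4474 and 2 at 24 h, 2313 and 0 from 12 h to 24 h, 10 and 6 lists at 12 h, and 5 and 6 lists at 24 h, and 1, 1, 1, 1 and 7 splits gave as many. For lists at consecutive time points no prediction was made. From 6 h to 12 h the real split gave 13 lists. A split of 6 h replicates 1, 3 and 4 against 6 h replicate 2 and the 12 h libraries also gave 13. From 12 h to 24 h the real split gave 7 lists. Setting 12 h replicate 1 with 24 h replicates 1 and 2 against the rest gave 8. Chance is therefore not excluded for those counts of lists.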

How the results depend on the processing

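Libraries thinned to equal totals, protein-coding genes alone, the library set as a term and the libraries of 1 set alone were chosen only after the results were seen; the other alternatives were planned. Contrasts are named by their later time point against 0 h unless both are given.

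Counts within 1.5 times those reported are not listed, and except where a reason is given the cause was not tested. With library totals only, 642 genes were lower at 24 h than at 12 h. With no filter, which tests 24049 genes in place of 13018, 496 genes were higher and 643 lower at 6 h, 661 were higher at 12 h than at 6 h, 520 calls were shared by 6 h and 12 h and 697 by 6 h and 24 h, and 10 lists passed at 24 h. With only the 2 groups compared, and so fewer libraries, 72 genes were higher and 72 lower at 6 h, and 463 higher and 579 lower at 12 h. With an estimated correlation 0 lists passed at 6 h and 2 at 12 h. At a threshold of 0.01, 71 calls were shared by 6 h and 12 h, 91 by 6 h and 24 h and 403 by 12 h and 24 h. Thinned to equal totals, 191 genes were higher at 6 h and 222 higher at 12 h than at 6 h, and 195 calls were shared by 6 h and 12 h and 252 by 6 h and 24 h.

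With the library set as a term, 3332 genes differed over the 4 time points. At 12 h 52 were higher and 115 lower, at 24 h 773 and 960, and at 12 h against 6 h 18 and 78; 6 lists passed at 12 h, and 91 calls were shared by 6 h and 12 h and 139 by 12 h and 24 h. The term raised the median standard error at 12 h from 0.103 to 0.176, and it also moved the fold changes, whose correlation across genes with those reported was 0.564; genes are not independent replicates. These 12 h log2 changes turned: ENSG00000196656 (0.469), RPL21P16 (7.64), ENSG00000213058 at 12 h against 0 h (-0.396), ENSG00000224114 (-0.337), RPL5P34 (-0.102), MT-ATP8 (-0.397), MT-ND6 (-0.104) and RPL5 (-0.032). The set tests of mitochondrially encoded genes (camera adjusted p = 0.231) and ribosomal protein genes (2.41e-16) turned at 12 h, as did that of ribosomal protein genes (2.03e-18) at 24 h. The log2 change of the gene CHEK2 at 24 h turned too (-0.069). The sets were found from the level of short transcripts, so for genes with short transcripts such a turn is not separate evidence. With the libraries of 1 set only, 76 genes were higher and 75 lower at 6 h, in a fit with fewer libraries.

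With each library left out in turn, the genes that differed over the 4 time points ran from 3878 to 5841. At 6 h 107 to 495 were higher and 112 to 434 lower, at 12 h 406 to 660 and 544 to 871, at 24 h 1480 to 2057 and 1688 to 2202, at 12 h against 6 h 113 to 728 and 274 to 910, and at 24 h against 12 h 614 to 838 and 622 to 819. Between 7 and 11 lists passed at 6 h, 8 and 11 at 12 h and 4 and 7 at 24 h. Calls shared ran from 133 to 428 for 6 h and 12 h, 147 to 602 for 6 h and 24 h, and 651 to 1128 for 12 h and 24 h. The set test of mitochondrially encoded genes at 12 h against 0 h ran from a camera adjusted p of 0.000893 without 0 h replicate 2 to 0.864 without 0 h replicate 1, where it turned.

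With replicate number as a block, 5137 genes differed over the 4 time points. Libraries of the same number were no more alike than others. The median correlation of their deviations from group means was -0.03, against 0.006 between different numbers. Single deviant libraries weigh on these values, so a pairing by number is not excluded. Each named gene was tested again under each setting that applies to its contrast, which gave 978 tests with a library left out and 1578 others. Calls were lost in 139 and 133 of these and gained in 1 and 2. Of 494 and 806 set tests, calls were lost in 15 and 32 and gained in 15 and 13. Thinned to equal totals, IFIT1 at 12 h against 0 h missed the threshold (log2 change 1.046, edgeR adjusted p = 0.209).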

Other observations

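The counts by abundance and the genes detected at equal depth were chosen only after the results were seen.

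Among 1334 tested protein-coding genes with a mean log2 CPM under 2, 265 were higher and 24 lower at 24 h than at 0 h, and with the library set as a term 50 and 7. Among 3431 with a mean log2 CPM over 6, 387 were higher and 1120 lower, and with the term 230 and 552. With every library drawn to 6157017 counts, 16134 to 16166 genes had a count in the 0 h libraries, 16089 to 16391 at 6 h, 16569 to 16900 at 12 h and 16780 to 17122 at 24 h.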
